A study of Mus musculus with 10 samples.

How the data were processed

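Bulk RNA sequencing was carried out on whole pancreas of mouse embryos at embryonic days 13.5 and 14.5. Each of the 10 libraries came from a pool of 3 to 12 pancreata, per the labels. The Fgf9-LacZ line carries a cassette inserted in the Fgf9 locus, and the groups were embryos labelled null and littermates labelled as having at least 1 intact copy. There were 3 control and 2 null-labelled libraries at each stage. The controls mix wild-type and heterozygous embryos, per the labels. RNA was extracted with TriZol and libraries were made from poly(A) RNA with a NEBNext Ultra II kit, per the labels' protocols.

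The deposited table holds raw read counts per gene for 54532 genes in 10 columns. Per the submitters' processing notes, reads were handled with TopHat, HTSeq and DESeq2 on the mm10 build, and versions are not given in the sources used here. The strand setting of the counting is likewise not given in the sources used here, so reads of overlapping antisense genes are not told apart. Near-identical copies such as the trypsins, amylases and alpha globins share reads, and values of single members are uncertain. Total counts ran from 17736769 to 22798257 per library. Mitochondrial genes took 2.3 to 3.39 percent of the counts and the highest single gene at most 1.29 percent.

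Counts were tested with edgeR 4.0.16 in R 4.3.3, by the quasi-likelihood F test with TMM normalization and a mean for each of the 4 groups. Genes were filtered by expression within groups, which left 18898 genes holding 99.91 percent of the counts. There were 6 residual degrees of freedom, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The standard error of a log2 fold change was approximated as its size divided by the square root of F. CPM are counts scaled to a common library size with TMM factors. Gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation and with fry beside it. All 29 lists, the comparisons and the rule for named genes were fixed before the data were examined. The rule took a fixed set of 15 genes, up to 10 genes per direction by fold change in each genotype comparison, up to 8 per direction between stages, and up to 4 called or 2 uncalled members per list. Genes chosen by fold change needed a mean of at least 1 CPM and no overlap between the groups.

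The alternatives were DESeq2 1.42.0, limma-voom, another normalization, no low-count filter, only the groups compared, a replicate block, and each library left out in turn. A few alternatives were added after seeing the data. One left out both null-labelled libraries numbered 1. Another joined the replicate block with an estimated correlation for the gene lists. The last dropped the filter but kept the spread estimated from filtered genes, because without a filter the prior degrees of freedom rose from 6.31 to infinite.

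The pairing of replicate numbers was checked before the fits were compared. Deviations from the group means of same-numbered control and null-labelled libraries correlated across genes at 0.36 and 0.14 at E13.5 and at 0.35 and 0.16 at E14.5. Each of these 4 values was over 0.1, and the numbers were taken as pairing the samples for genotype. The main fit, fixed beforehand, has no block, and the fit with the replicate number as a block was run as an alternative to it. The evidence is thin, because 2 libraries deviate from their mean as mirror images, and the null-labelled libraries numbered 2 correlated more with control 3, at 0.25 and 0.22. The blocked fit leaves 2 residual degrees of freedom. Between stages the control values were 0.3, 0.04 and 0.16, and the numbers were not taken as pairing.

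Replicate libraries of a group differed far beyond counting noise, with a chi-square per gene of 12.1 to 48.4, so none was counted as a duplicate. On simulated data for the E13.5 genotype comparison, with 18345 genes, edgeR recovered 54 of 100 genes changed 2-fold and 93 of 100 changed 4-fold, with 5 false calls. For the E14.5 genotype comparison, with 18307 genes, it recovered 58 and 83 of 100 with 11 false calls. Simulated libraries vary independently, so they do not carry the shared structure of the real ones. Coordinates are from GENCODE M21 on GRCm38, which is mm10, and 181 of 181 named genes matched by identifier.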

Results

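Whole pancreas was profiled at embryonic days 13.5 and 14.5 in embryos labelled null for Fgf9, which encodes a secreted fibroblast growth factor, and in littermate controls. Each stage had 3 control and 2 null-labelled libraries, every one from a pool of pancreata. Control pools held 6 to 12 pancreata, and null-labelled pools held 3 to 7. Total counts were 20049814 to 21082589 in E13.5 controls and 18004724 to 22798257 in E13.5 null-labelled libraries. They were 18321734 to 19254562 in E14.5 controls and 17736769 to 20842606 in E14.5 null-labelled libraries. The labels do not say whether the pools of a group came from separate litters, so p-values measure the spread between these pools.

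The targeted gene was examined first as a check of the labels. Fgf9 (ENSMUSG00000021974, chromosome 14, 58070547 to 58112720) was at 15.3 ± 3.7 CPM (SD, n = 3) in E13.5 controls and 6.61 ± 1.5 CPM (SD, n = 2) in E13.5 null-labelled libraries. The difference was -1.21 on the log2 scale (SE 0.36, edgeR adjusted p = 0.29), and both null-labelled libraries lay below all controls. With the replicate number as a block it was -1.13 (edgeR adjusted p = 0.026). At E14.5 controls were at 9.79 ± 3.5 CPM (SD, n = 3) and null-labelled libraries at 8.93 ± 3.9 CPM (SD, n = 2), a difference of -0.14 (SE 0.35, edgeR adjusted p = 0.96) with overlapping libraries. Without E14.5 control 1 that difference was 0.18, and without E14.5 null 2 it was 0.26. Gene counts do not show which part of the transcript the insertion leaves, so the count neither proves nor refutes the labels. The groups are therefore called null-labelled in every comparison.

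At E13.5 the genes that fell in null-labelled pancreas were led by transcription factors of the mesenchyme that gives rise to the spleen. Tlx1 (ENSMUSG00000025215, chromosome 19, 45150680 to 45156943), which is required for spleen formation, was at 17.4 ± 1.8 CPM (SD, n = 3) in controls and 0.284 ± 0.28 CPM (SD, n = 2) in null-labelled libraries, 63.5-fold lower (edgeR adjusted p = 0.00041). Barx1 (ENSMUSG00000021381, chromosome 13, 48662998 to 48666507), a homeobox factor of stomach and spleen mesenchyme, was at 89.3 ± 12 against 7.03 ± 1.5 CPM, 12.7-fold lower (edgeR adjusted p = 1.2e-05). Nkx3-2 was 5.41-fold lower (edgeR adjusted p = 0.034). Of the 10 spleen mesenchyme genes tested 3 fell, 0 rose and 7 did not pass the test, and 5 fell when adjusted over the list alone. The list as a whole fell (camera adjusted p = 6.3e-26, and adjusted p = 0.0084 with an estimated correlation). Its median log2 fold change was -0.57. At either stage, counts of pooled whole pancreas do not tell lower expression per cell from fewer such cells in the pools, in the embryo or through dissection. Nkx2-5 had a mean of 3.55 CPM in controls and 0.123 CPM in null-labelled libraries and did not pass over all genes (edgeR adjusted p = 0.088), but did so with the replicate block (edgeR adjusted p = 0.005).

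Other genes with large falls at E13.5 were the synaptotagmin gene Syt6, 10.2-fold, and Kazald1, 6.92-fold. Wnt5a (chromosome 14, 28504750 to 28527448), a secreted Wnt ligand, was at 62.3 ± 14 CPM (SD, n = 3) in controls and 9.68 ± 1.3 CPM (SD, n = 2) in null-labelled libraries, 6.42-fold lower (edgeR adjusted p = 0.00075). Slitrk5, Nfam1, Htra1 and Lhx9 fell 4.61-fold, 3.75-fold, 3.61-fold and 3.32-fold. Among genes with the largest rises were Trac, 9.2-fold, Oprk1, 5.15-fold, Angpt1, the ligand of the endothelial Tie2 receptor, 4.56-fold, and the guidance ligand gene Sema3e, 4.04-fold. Trac (chromosome 14, 54220521 to 54224206) lies on the same chromosome as Fgf9. Whether its rise at either stage goes with sequence carried beside the inserted cassette was not tested. Art4, Dsc3, Thbs4, Col4a6 and Itga2b rose 5.16-fold, 4.15-fold, 4.06-fold, 3.38-fold and 3.32-fold.

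Fibroblast and contractile genes were higher in null-labelled libraries at E13.5. Lum and Dcn, which encode small proteoglycans of the matrix, rose 2.85-fold and 2.15-fold, and were the 2 called of 18 fibroblast genes, with 4 higher and 1 lower when adjusted over the list alone. Smooth muscle actin Acta2 (chromosome 19, 34241090 to 34255590) rose 3.17-fold and was the only 1 of 12 smooth muscle genes called, with 5 higher and 2 lower when adjusted over the list alone. With the replicate block 7 fibroblast genes were higher and 1 lower, and 4 smooth muscle genes were higher and 2 lower. The fibroblast list rose (camera adjusted p = 2.2e-07) and so did the smooth muscle list (camera adjusted p = 1.9e-05). Both had adjusted p = 0.28 with an estimated correlation.

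Of the 13 FGF feedback genes tested at E13.5, which are switched on by FGF signalling, only Spry1 fell, by 2.05-fold (edgeR adjusted p = 0.016), and 2 fell when adjusted over the list alone. The list fell (camera adjusted p = 0.00075, and adjusted p = 0.15 with an estimated correlation). Spry4 had a log2 fold change of -0.65 and Dusp6 of 0.1, and neither passed. In the Wnt list Wnt5a and Notum fell, 2 of 17 genes tested, with 2 higher and 3 lower when adjusted over the list alone (camera adjusted p = 0.0043, and adjusted p = 0.28 with an estimated correlation). Egr1, an immediate early gene, rose 2.62-fold, the only 1 of 11 immediate early and stress genes called, over all genes and adjusted over the list alone (camera adjusted p = 0.015, and adjusted p = 0.18 with an estimated correlation).

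Endothelial genes were higher as a list at E13.5, with a median of 0.31 (camera adjusted p = 4.7e-07, and adjusted p = 0.045 with an estimated correlation). None of its 13 genes was called over all genes, 3 were with the replicate block, and 4 were higher when adjusted over the list alone, among them Tie1 at 1.49-fold. The Notch list had a median of 0.31 (camera adjusted p = 5.4e-05, and adjusted p = 0.071 with an estimated correlation), with 0 of 14 genes called, 4 higher with the replicate block, and 2 higher when adjusted over the list alone. In the BMP and TGF-beta list Tgfbi fell 3.26-fold while 5 genes were higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.0045 for a higher list, and adjusted p = 0.24 with an estimated correlation). The erythroid list had a median of 0.6 with 3 of 12 genes higher when adjusted over the list alone (camera adjusted p = 1.6e-05, and adjusted p = 0.11 with an estimated correlation). The mesothelium list had a median of -0.14, with 1 gene higher and 2 lower when adjusted over the list alone (camera adjusted p = 0.02, and adjusted p = 0.56 with an estimated correlation). With the replicate block 0 genes of the mesothelium list were higher and 5 lower. In 13 lists, among them FGF ligands and receptors, Hedgehog, retinoic acid, hypoxia and the stomach, intestine, gonad and sex-linked lists, and the progenitor, duct and endocrine lists, camera adjusted p ran from 0.098 to 0.8. With the replicate block the progenitor list passed (camera adjusted p = 0.024, and adjusted p = 0.63 with an estimated correlation).

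None of the epithelial genes fixed in advance passed at E13.5. Pdx1 was at 71.2 ± 14 CPM (SD, n = 3) in controls and 71.7 ± 11 CPM (SD, n = 2) in null-labelled libraries. The log2 fold changes were -0.61 for Ptf1a, 0.16 for Sox9, 0.01 for Neurog3, -0.08 for Cpa1, -0.38 for Ins2 and -0.21 for Gcg, with SE from 0.27 to 0.51. None of the 16 progenitor, 26 acinar, 12 duct, 13 endocrine progenitor or 20 hormone-positive endocrine genes passed, over all genes or adjusted over the list alone. Genes such as Gata6 and Insm1 passed with the replicate block and were higher. The acinar list had a median of -0.36 (camera adjusted p = 0.0045, and adjusted p = 0.71 with an estimated correlation). The cell cycle list had a median of -0.22 with 0 of 26 genes called (camera adjusted p = 5e-05, and adjusted p = 0.42 with an estimated correlation).

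In all, edgeR called 25 genes higher and 33 lower in null-labelled libraries at E13.5. With the replicate block the counts were 391 and 175, and without both null-labelled libraries numbered 1 they were 8 and 18. The higher and lower counts were 6 and 11, 4 and 10, and 8 and 17 without E13.5 control 1, 2 and 3, 1 and 6 without E13.5 null 1, 4 and 8 without E13.5 null 2, 85 and 43 without E14.5 control 1, 20 and 18 without E14.5 control 2, and 60 and 50, and 62 and 50, without E14.5 null 1 and 2, and 4 of the 20 genes with the largest changes (Barx1, Htra1, Tlx1 and Wnt5a) stayed called without each of the 10 libraries.

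**Figure D1:**
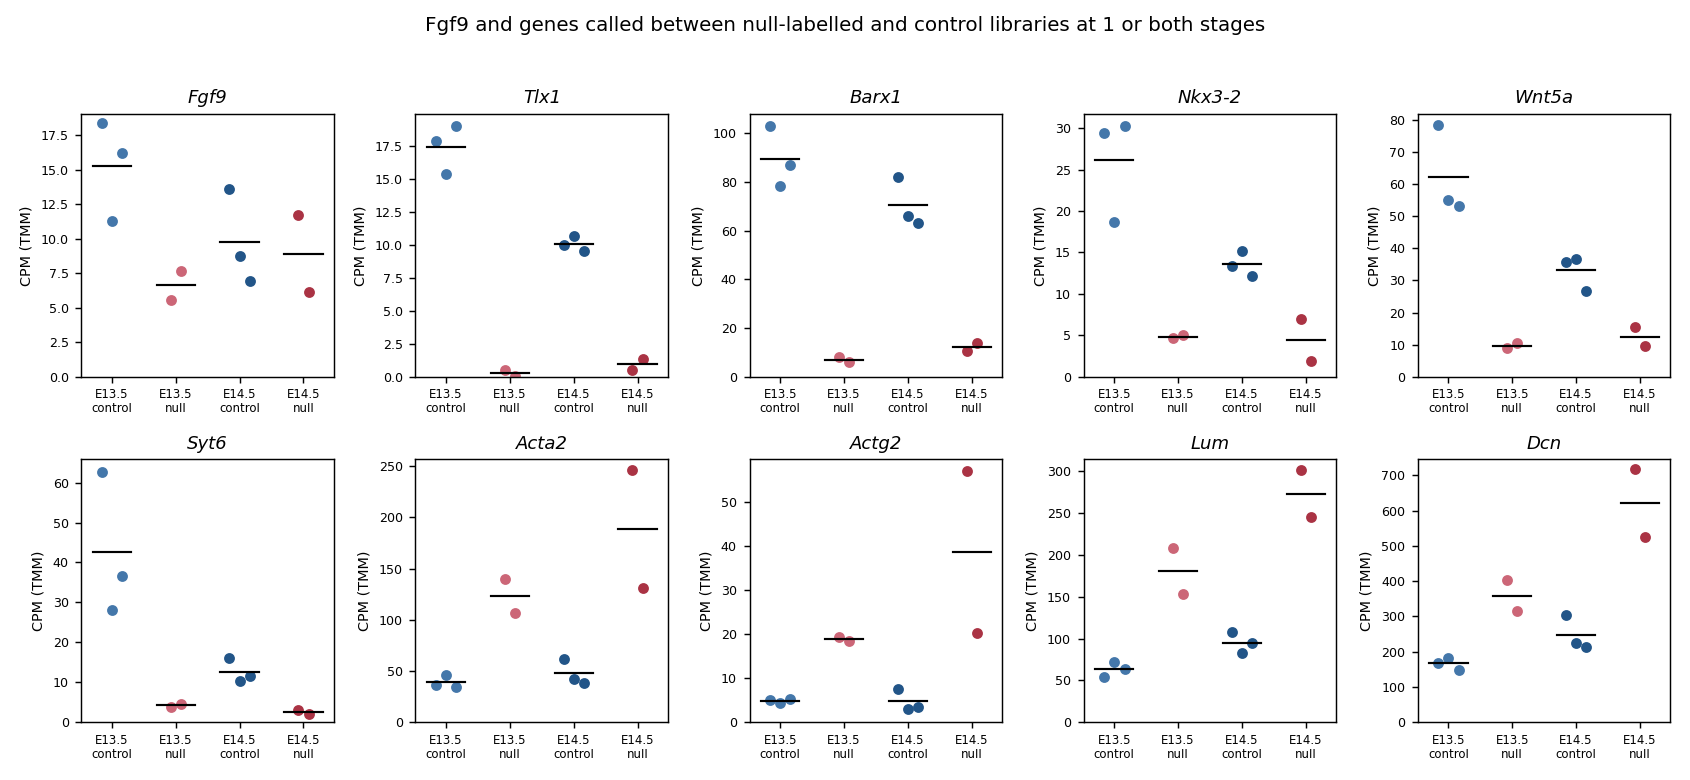
Normalised counts (CPM scaled by TMM, vertical axes from 0) of Fgf9 and 9 genes in the 10 libraries, with a point per library and a bar at each group mean. Tlx1 and Barx1 are lower in every null-labelled library than in every control of the same stage, while Acta2, Lum and Dcn are higher, and Fgf9 overlaps at E14.5.

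At E14.5 some of the spleen mesenchyme genes were again lower in null-labelled pancreas. Barx1 was at 70.5 ± 10 CPM (SD, n = 3) in controls and 12.2 ± 2.2 CPM (SD, n = 2) in null-labelled libraries, 5.76-fold lower (edgeR adjusted p = 0.00021). Tlx1 was at 10.1 ± 0.55 against 0.925 ± 0.6 CPM, 10.7-fold lower (edgeR adjusted p = 0.015). These were 2 of 10 genes called, with 4 lower and 1 higher when adjusted over the list alone. The 4 were Tlx1, Barx1, Nkx2-5 and Nkx3-2, and the higher gene was Tcf21. The list fell, with a median of -0.26 (camera adjusted p = 1.7e-09, and adjusted p = 0.1 with an estimated correlation). The neurotrophin receptor gene Ntrk2 fell 3.97-fold, Syt6 5.11-fold, Lhx9 4.55-fold and the collagen gene Col7a1 3.96-fold.

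The rises at E14.5 were led by Trac, 10.1-fold, the mesothelial gene Msln, 9.92-fold, and contractile genes. Msln was the 1 called of 14 mesothelium genes, with 3 higher and 1 lower when adjusted over the list alone. With the replicate block 3 were higher and 4 were lower, namely Lrrn4, Muc16, Wt1 and Aldh1a2. Actg2 rose from 4.68 ± 2.5 CPM (SD, n = 3) to 38.5 ± 26 CPM (SD, n = 2), and Acta2 rose 3.96-fold. These were the 2 called of 12 smooth muscle genes, with 9 higher when adjusted over the list alone, and the list rose (camera adjusted p = 2.1e-16, and adjusted p = 0.1 with an estimated correlation). Lum rose 2.87-fold and Dcn 2.51-fold, 2 of 18 fibroblast genes, with 7 higher and 1 lower when adjusted over the list alone (camera adjusted p = 1.2e-11, and adjusted p = 0.12 with an estimated correlation). With the replicate block 5 smooth muscle genes were higher and 0 lower, and 8 fibroblast genes were higher and 1 lower. Oprk1, Clec11a, Anxa1, Col4a6, Edn1 and Ackr3 rose 6.84-fold, 3.43-fold, 3.31-fold, 3.31-fold, 3.11-fold and 2.9-fold. None of the epithelial genes fixed in advance passed at E14.5. Ins2 had a log2 fold change of 0.54 (edgeR adjusted p = 0.84), which with the replicate block was 0.7 (edgeR adjusted p = 0.0084). None of the progenitor, acinar, duct or endocrine genes passed, over all genes or adjusted over the list alone. In the blocked fit 4 acinar genes (Cpb1, Cela2a, Try5 and Reg1) and 5 hormone-positive endocrine genes (Ins1, Ins2, Iapp, Pcsk2 and Scg2) passed and were higher, and Nr5a2, Cdh1 and Runx1t1 were lower. These genes were named after their values were seen. The null-labelled libraries parted here, with an acinar median log2 difference from the control mean of -0.9 in E14.5 null 1 and 0.79 in E14.5 null 2, and a hormone-positive median of -0.31 and 0.73. The controls parted too. On the first principal component E14.5 control 1 lay at -5.82 and E14.5 null 1 at -11.4, against 54.2 for E14.5 null 2. Against the control of the same number, the acinar medians were 0.17 and -0.06, and the hormone-positive medians 0.31 and 0.66. The progenitor list had a median of -0.27 (camera adjusted p = 0.0044, and adjusted p = 0.57 with an estimated correlation) and without E14.5 null 1 its camera adjusted p was 0.87. The cell cycle list had a median of -0.15 (camera adjusted p = 0.0025, and adjusted p = 0.56 with an estimated correlation).

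The BMP and TGF-beta list rose at E14.5, with 0 of 16 genes called over all genes, 3 higher and 2 lower with the replicate block, and 7 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.00012, and adjusted p = 0.1 with an estimated correlation). The endothelium list had a median of 0.14 (camera adjusted p = 0.0041, and adjusted p = 0.1 with an estimated correlation). The immediate early and stress list had a median of 0.23 (camera adjusted p = 0.013, and adjusted p = 0.12 with an estimated correlation), and 0.053 by camera with the replicate block. The FGF feedback list had a median of -0.05 and did not pass (camera adjusted p = 0.2), and Spry1 was at a log2 fold change of -0.64 (edgeR adjusted p = 0.14, and 0.032 with the replicate block). In 15 lists, those of FGF feedback, FGF ligands and receptors, mesothelium, acinar, duct, both endocrine groups, Hedgehog, Wnt, retinoic acid, Notch, hypoxia, erythroid, stomach and gonad genes, camera adjusted p ran from 0.1 to 0.55. With the replicate block 4 of these passed, namely hormone-positive endocrine (camera adjusted p = 2.8e-07, higher), Wnt (0.0094, lower), FGF feedback (0.029, lower) and erythroid (0.011, higher), at adjusted p from 0.32 to 0.36 with an estimated correlation in that fit.

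At E14.5 edgeR called 15 genes higher and 6 lower. With the replicate block the counts were 342 and 122, and without both null-labelled libraries numbered 1 they were 2 and 11. The higher and lower counts were 7 and 5 without E13.5 control 2 or 3, 234 and 25 without E14.5 control 1, 0 and 2 without E14.5 control 2, 0 and 3 without E14.5 control 3, 6 and 11 without E14.5 null 1 and 119 and 12 without E14.5 null 2, and Barx1 and Ntrk2 were the 2 of 16 genes with the largest changes that stayed called without each of the 10 libraries.

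Markers of other tissues moved with the null labels. Albumin transcript Alb was at 12.6 ± 9.1 CPM (SD, n = 3) in E13.5 controls and 74.7 ± 30 CPM (SD, n = 2) in null-labelled libraries, and at 19.5 ± 17 against 115 ± 1.7 CPM at E14.5. None of the 12 liver genes passed at a single stage, but 4 at E13.5 and 6 at E14.5 did so with the replicate block, and 7 at E13.5 and 8 at E14.5 were higher when adjusted over the list alone. The liver list rose at E13.5 (camera adjusted p = 6.6e-09, and adjusted p = 0.071 with an estimated correlation) and at E14.5 (camera adjusted p = 2.7e-10, and adjusted p = 0.1 with an estimated correlation). Skeletal muscle genes such as Myh3 had means of 3.2 against 13.7 CPM at E13.5 and 2.17 against 26.7 CPM at E14.5. The skeletal muscle list rose at E13.5 (camera adjusted p = 0.012, and adjusted p = 0.56 with an estimated correlation) and at E14.5 (camera adjusted p = 3e-08, and adjusted p = 0.14 with an estimated correlation). None of its 9 genes passed at a single stage, while 4 were higher and 1 lower at E13.5 and 5 higher at E14.5 when adjusted over the list alone, and 2 higher and 1 lower, and 4 higher, with the replicate block. The list lost its call without E13.5 null 1 at E13.5 (camera adjusted p = 0.6) and without E14.5 null 1 at E14.5 (camera adjusted p = 0.21). The neural and glial list was higher at both stages, with medians of 0.83 and 1.05 (camera adjusted p = 6.5e-09 and 3.1e-10, and adjusted p = 0.15 and 0.1 with an estimated correlation). None of its 13 genes passed at a single stage, while 5 at E13.5 and 8 at E14.5 were higher when adjusted over the list alone, and 9 and 7 with the replicate block. Macrophage genes had a median of 0.82 at E14.5, with 0 of 13 called, 6 higher with the replicate block and 10 higher when adjusted over the list alone (camera adjusted p = 5.3e-13, and adjusted p = 0.1 with an estimated correlation). The intestine list had a median of 1.79 at E14.5 over 5 genes tested (camera adjusted p = 0.01, and adjusted p = 0.1 with an estimated correlation). At E14.5 the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had no count in null-labelled library 2, a pool of 3 pancreata, and were at 2.85 to 7.92 CPM in null-labelled library 1 (camera adjusted p = 1.7e-06 for the sex-linked list, and adjusted p = 0.1 with an estimated correlation). These 4 were chosen after their values were seen. Y-linked transcript comes from male embryos, so these values follow the sex of the pooled embryos and do not mark a tissue. Kdm5d, Ddx3y and Uty lay below every control in both E14.5 null-labelled pools, so sex and genotype are not told apart at that stage.

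**Figure D2:**
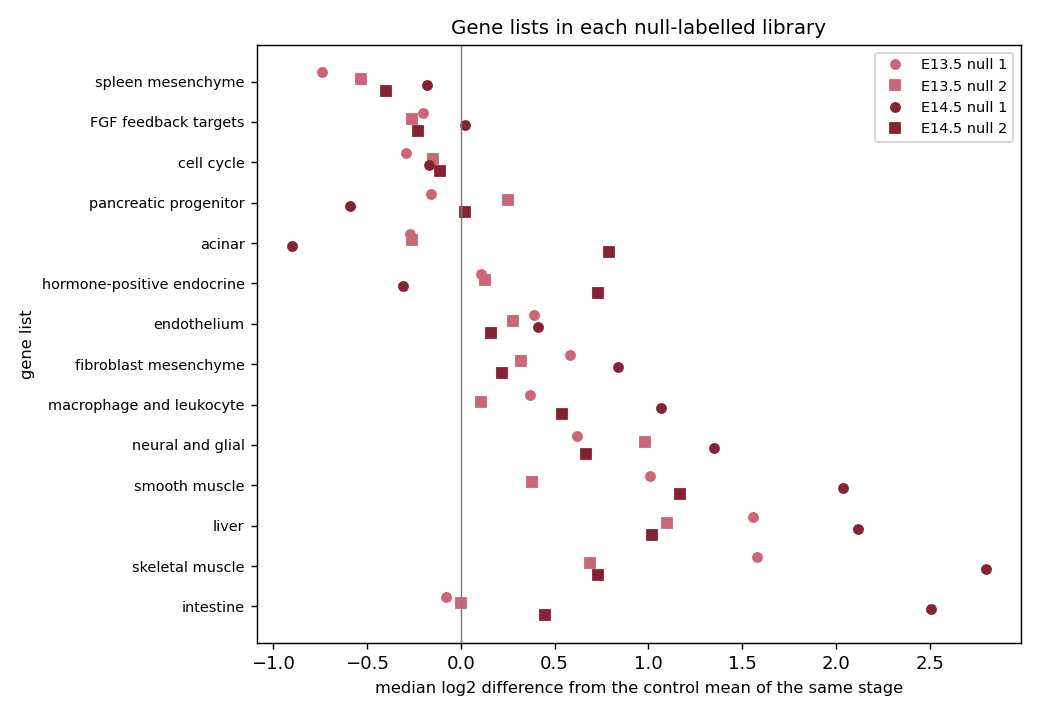
Median log2 difference of each gene list (vertical axis) between a null-labelled library and the mean of the controls of its stage (horizontal axis), with a point per null-labelled library. The liver list lies between 1.02 and 2.12 in the 4 libraries, and the intestine list reaches 2.51 in E14.5 null 1 alone.

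The fold changes of the 2 stages were compared next. Of the 58 genes called at E13.5, 55 had the same direction at E14.5, and all 21 called at E14.5 had the same direction at E13.5. The lists shared 9 higher genes, where independent lists would share 0.02, and 6 lower genes, where they would share 0.01. Both comparisons come from the same fit with a shared spread for each gene. Independent lists are thus not a fair benchmark, and this excess can overstate the agreement of the stages. Across all genes tested, which are not independent replicates, the log2 fold changes of the 2 stages correlated at 0.3. Averaged over both stages, 275 genes were higher and 79 lower in null-labelled libraries, against 777 and 325 with the replicate block and 47 and 54 without both null-labelled libraries numbered 1. In the average Tlx1, Nkx2-5, Barx1 and Nkx3-2 fell, as did Aldh1a2 and Crabp1 of the retinoic acid pathway, by 1.99-fold and 1.94-fold, while Tgfb1, Tgfb2 and Tgfb3 rose by 1.49-fold to 2.11-fold and Tgfbi of the same list fell 2.16-fold. The glial gene Sox10 rose 1.97-fold. Smooth muscle genes Cnn1, Actg2 and Myh11 rose 7.12-fold, 5.64-fold and 4.02-fold, and the skeletal muscle genes Myh3, Actc1 and Acta1 rose 7.2-fold, 6.78-fold and 6.44-fold. Against the mean of all controls of the stage, both lists lay higher in the null-labelled libraries numbered 1. Median log2 differences from the control mean in libraries 1 and 2 were 1.01 and 0.38 at E13.5 for smooth muscle, and 2.04 and 1.17 at E14.5. For skeletal muscle they were 1.58 and 0.69 at E13.5, and 2.8 and 0.73 at E14.5. Against the control of the same number, the smooth muscle medians in pairs 1 and 2 were 1.25 and 0.58 at E13.5. At E14.5 they were 1.53 and 1.63, without an excess in pair 1. The skeletal muscle medians in these pairs were 1.12 and 0.79 at E13.5, and 2.4 and 0.61 at E14.5. Liver genes Apob and Alb rose 8.22-fold and 5.89-fold. In the average the spleen mesenchyme, endothelium and liver lists kept their calls with an estimated correlation (adjusted p = 0.019, 0.049 and 0.049), as did spleen mesenchyme and endothelium at E13.5, and these 5 held of the 60 list calls outside the comparison of null-labelled stages. In the blocked fit, on 2 residual degrees of freedom, their adjusted p with an estimated correlation ran from 0.25 to 0.32. The acinar list in the average had camera adjusted p = 0.035, and 0.54 with the replicate block, while the blocked fit called the hormone-positive endocrine list higher (camera adjusted p = 0.00013) and the mesothelium and gonad lists lower (camera adjusted p = 0.0016 and 0.034), which had adjusted p = 0.41, 0.29 and 0.29 with an estimated correlation in that fit. The averaged higher and lower counts were 163 and 59, 130 and 48, and 131 and 57 without E13.5 control 1, 2 and 3, 99 and 41, and 141 and 39, without E13.5 null 1 and 2, 562 and 117, 117 and 49, and 120 and 55 without E14.5 control 1, 2 and 3, and 118 and 69, and 434 and 79, without E14.5 null 1 and 2.

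The interaction between genotype and stage called 0 genes by edgeR, with 454 at an unadjusted p under 0.05. On simulated data this test recovered 20 of 100 genes changed 2-fold and 67 of 100 changed 4-fold, with 4 false calls. The absence of calls therefore does not show that the stages respond alike. DESeq2 called 4 higher, Ctsk, Htra3, Rtl3 and the predicted gene Gm18194, and 0 lower, and limma-voom called 0. The edgeR fit with the replicate block called 5 higher, Htra3, Rtl3, Smoc2, Tgfbi and Prss3, and 8 lower, among them Angpt1 and Fn1. These genes were named after their values were seen. By camera the blocked fit also called the acinar, hormone-positive endocrine and intestine lists higher in the interaction (adjusted p = 4.2e-05, 0.0072 and 0.034) and the duct list lower (adjusted p = 0.00095). With an estimated correlation in that fit these had adjusted p from 0.42 to 0.72.

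Between E13.5 and E14.5 the control pancreas gained digestive enzyme and hormone transcripts. Cpb1 (ENSMUSG00000011463, chromosome 3, 20248264 to 20275733), a pancreatic carboxypeptidase, went from 2.84 ± 0.38 to 106 ± 93 CPM (SD, n = 3 in each), 37.4-fold (edgeR adjusted p = 0.033). The elastase gene Cela3b rose 49.7-fold, and Try4, Rnase1, Try10, Prss1, Amy2a1 and Aqp12 rose 124-fold, 83.3-fold, 83.1-fold, 75.7-fold, 51.9-fold and 110-fold, with trypsin and amylase members sharing reads. Of 26 acinar genes tested 16 rose and 0 fell, with 21 higher when adjusted over the list alone, and the list rose (camera adjusted p = 1.2e-34, and adjusted p = 0.32 with an estimated correlation). Ptf1a, the acinar transcription factor, rose 3.02-fold. E14.5 control 1 stood apart from the other E14.5 controls, with Cpb1 at 10.3 CPM against 112 and 196, and Cela3b at 16.3 CPM against 112 and 312. On the first principal component it lay at -5.82 against 56.6 and 58. Without it both genes stayed called.

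Insulin gene Ins2 (ENSMUSG00000000215, chromosome 7, 142678656 to 142743381) went from 16.6 ± 5.1 to 207 ± 98 CPM (SD, n = 3 in each), 12.4-fold (edgeR adjusted p = 0.012). Ins1, Sst and Iapp rose 10.7-fold, 21.6-fold and 5.46-fold. Of 20 hormone-positive endocrine genes 5 rose and 0 fell, with 10 higher when adjusted over the list alone (camera adjusted p = 3.6e-13, and adjusted p = 0.42 with an estimated correlation). The embryonic globins Hbb-bh1, Hbb-y and Hba-x fell 4.32-fold, 4.01-fold and 3.52-fold, and the adult globin Hbb-bs rose 2.88-fold. Hsd3b6, Crabp2, Bves, Nfam1 and Syt6 fell 5.21-fold, 3.98-fold, 3.75-fold, 3.63-fold and 3.37-fold. Of 12 hypoxia genes Egln3 and Pdk1 rose, with 8 higher when adjusted over the list alone (camera adjusted p = 4.2e-08, and adjusted p = 0.32 with an estimated correlation).

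The spleen mesenchyme list fell between the stages in controls with a median of -0.56, 0 of 10 genes called and 4 lower when adjusted over the list alone (camera adjusted p = 0.00015, and adjusted p = 0.32 with an estimated correlation). Camera adjusted p ran from 0.068 to 0.97 in the other 25 lists.

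Between E13.5 and E14.5 hormone transcripts also rose in null-labelled libraries. Iapp rose from 17.9 ± 1.2 to 107 ± 50 CPM (SD, n = 2 in each), and Ins1, Ins2 and Sst also rose, 4 of 20 hormone-positive endocrine genes, with 9 higher when adjusted over the list alone (camera adjusted p = 2.2e-11, and adjusted p = 0.31 with an estimated correlation). Of 26 acinar genes Rbpjl and Spink1 rose, with 24 higher when adjusted over the list alone (camera adjusted p = 1.5e-33, and adjusted p = 0.31 with an estimated correlation). Msln and Krt19 rose in the mesothelium list (camera adjusted p = 2.2e-05, and adjusted p = 0.31 with an estimated correlation), and Hba-x fell from 219 ± 62 to 34.5 ± 3.5 CPM (SD, n = 2 in each). Of the other lists, hypoxia, sex-linked, endocrine progenitor, erythroid, smooth muscle, Notch, macrophage, intestine and skeletal muscle passed by camera (adjusted p from 2.3e-05 to 0.039), and none of them with an estimated correlation (adjusted p from 0.31 to 0.69).

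In controls 147 genes rose and 64 fell between the stages, and in null-labelled libraries 38 rose and 9 fell. The difference between these effects is the interaction above, which called 0 genes by edgeR but missed most 2-fold changes in simulation. The control counts were 1 and 0, 0 and 0, and 3 and 1 without E13.5 control 1, 2 and 3, 728 and 482, 0 and 0, and 11 and 4 without E14.5 control 1, 2 and 3, 76 and 35, and 75 and 35, without E13.5 null 1 and 2, and 324 and 162, and 316 and 161, without E14.5 null 1 and 2. The null-labelled counts were 7 and 5, and 0 and 0, without E13.5 null 1 and 2, 140 and 41, and 23 and 7, without E14.5 null 1 and 2, 20 and 7, 14 and 7, and 13 and 6 without E13.5 control 1, 2 and 3, and 199 and 67, and 17 and 7, without E14.5 control 1 and 3. None of the 16 genes with the largest changes between stages stayed called without each of the 10 libraries.

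**Figure D3:**
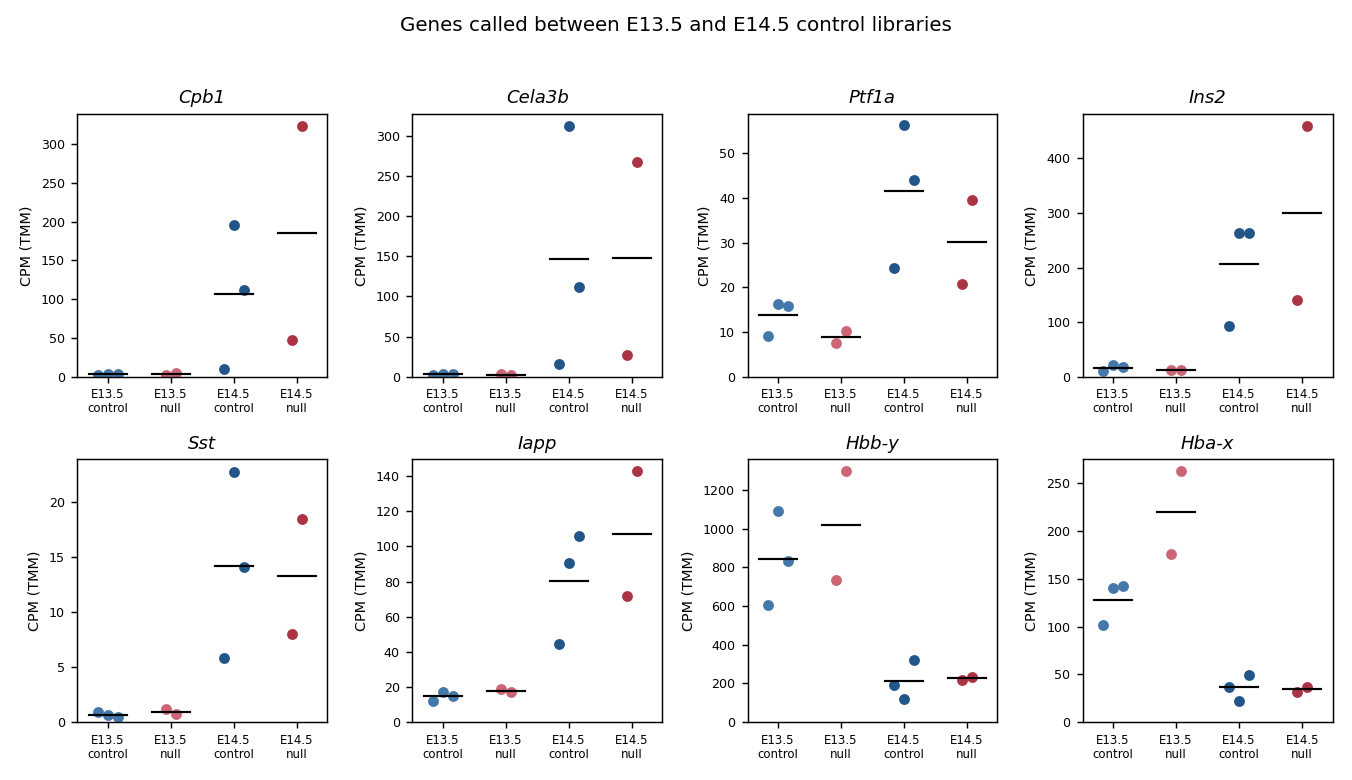
Normalised counts (CPM scaled by TMM, vertical axes from 0) of 8 genes called between control libraries of the 2 stages, with a point per library and a bar at each group mean. Cpb1, Cela3b, Ins2, Sst and Iapp are higher at E14.5 and the embryonic globins Hbb-y and Hba-x are lower, and E14.5 libraries spread widely.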

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

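All tests of explanations in this part were chosen after the results were seen. Each SE in them was taken over genes, which vary together, and does not measure the spread between libraries. The genotype effect differed between E13.5 and E14.5 for 9 gene lists by camera at the preset correlation, and for none with an estimated correlation. The adjusted p was 1.4e-05 for spleen mesenchyme, 0.0011 for mesothelium, 5.2e-05 for smooth muscle, 0.0027 each for pancreatic progenitor, Notch pathway and skeletal muscle, 0.0076 for erythroid, 3.9e-07 for macrophage and leukocyte, and 5.9e-07 for sex-linked genes. With an estimated correlation these adjusted p-values ran from 0.23 to 0.56. The median difference was 0.74 for spleen mesenchyme, 0.68 for smooth muscle, 0.54 for macrophage and leukocyte genes and -3.03 for sex-linked genes. The sex-linked difference follows the sex of the embryos pooled at E14.5 and is not read as an effect of genotype. Without E14.5 null 1 the smooth muscle difference had an adjusted p of 0.51, and the skeletal muscle difference turned direction with 0.43. The skeletal muscle adjusted p was 0.26 without E13.5 null 2 and 0.059 without E14.5 control 3.

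Smooth muscle and fibroblast genes were higher in null-labelled libraries. A lower share of epithelium would raise the markers of other cell types alike. The mean log2 fold change of the smooth muscle list exceeded that of the endothelium list by 0.95 (SE 0.3). Its median difference from the control mean was larger in each null-labelled library, but only 0.38 against 0.28 in E13.5 null 2. With endothelium as the reference, these values go against a lower share of epithelium as the whole cause for these genes, without a measure of the spread between libraries. The averaged mean of the endothelium list, 0.28, lay above that of the mesothelium list, 0.05. It lay below those of the erythroid list, 0.48, and the neural and glial list, 0.9. Other references were not tested, so the reading holds for this reference alone. For the fibroblast list a lower share of epithelium stays open, as this list exceeded the endothelium list by 0.2 (SE 0.14). Gut or muscle tissue in the pools numbered 1 alone is not decided, because leaving these out keeps 1 null-labelled library per stage. Without them the mean log2 fold change of the smooth muscle list over both stages was 0.77 (SE 0.23). Its mean in both null-labelled libraries numbered 2 lay above every control of the stage. Its median difference from the control mean there was 0.38 at E13.5, with 8 of 12 genes higher, and 1.17 at E14.5, with 9 of 12. For the fibroblast list the mean log2 fold change was 0.22 (SE 0.13), and only 1 of the 2 libraries lay above every control. Such tissue in all 4 null-labelled pools, which was not tested, and an effect of genotype also stay open.

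Liver transcripts were higher in null-labelled libraries. With endothelium again the only reference, the mean of the liver list exceeded that of the endothelium list by 1.06 (SE 0.31). This goes against a lower share of epithelium as the whole cause, with the same limits of that reference and of the SE. Liver tissue carried into the pools stays open, because the lowest number of the 12 liver genes above the control mean in a null-labelled library was 9, between the bounds set for and against it. An effect of genotype on these transcripts was not tested apart from it.

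Fgf9 counts were retained in null-labelled libraries. A swap of the labels of single libraries, or at 1 stage alone, is argued against by the genes called at the other stage, signed by their direction there. Scored with these, the smallest gap of a null-labelled library above every control of its stage was 1.04 on the log2 scale (SE 0.1). An exchange of the labels at both stages is not decided. The FGF feedback list, which FGF signalling switches on, ran against it. Its averaged mean log2 fold change in null-labelled libraries was -0.18 (SE 0.08). The evidence is limited, as its camera adjusted p of 0.0066 was 0.17 with an estimated correlation, and its median in E14.5 null 1 was 0.02. Fgf9 itself was at -0.67 averaged (edgeR adjusted p = 0.27) and -0.75 with the replicate block (edgeR adjusted p = 0.024). At E14.5 alone it was -0.36 with the block (edgeR adjusted p = 0.63). There it ran from -0.68 to 0.26 with single libraries left out of the main fit. Its count does not decide on the labels. Counting of transcript outside the inserted cassette stays open, since the null-labelled libraries had a mean count of 154 and gene counts do not show where in the gene reads lie.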

How the results depend on the processing

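Alternatives other than those added after seeing the data were fixed before the data were examined. With DESeq2 size factors each count of called genes stayed within 1.5 times, and all 120 called named genes and 60 called lists kept their calls. limma-voom kept 88 of the 120 genes, the replicate block 89 of 89 within stages and 31 of 31 across stages, and the fit without both null-labelled libraries numbered 1 kept 38 of 89. With single libraries left out the number kept ran from 52 of 120, without E14.5 control 2, to 120 of 120, without E14.5 control 1. Where an arm was left with 1 library, that library was assumed to vary like the other groups. Of the 60 list calls outside the comparison of null-labelled stages, 5 held with an estimated correlation and 11 with fry. With the replicate block and an estimated correlation together, on 2 residual degrees of freedom, 0 of 56 held. The pairs below give genes higher and lower, and unless stated the cause was not tested.

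Without a low-count filter the counts were 337 and 122 for genotype at E13.5, 443 and 104 at E14.5, 759 and 204 averaged, 35 and 16 for the interaction, 813 and 479 between control stages and 609 and 279 between null-labelled stages. Prior degrees of freedom went from 6.31 to infinite, which removes the spread of single genes, and the highest spread went from 53.6 to 1.58. With the spread of the filtered genes kept, the counts were 13 and 17 at E13.5, 163 higher averaged, 34 and 15 between control stages and 18 higher between null-labelled stages.

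DESeq2 called 157 and 97 at E13.5, 244 and 46 at E14.5, 591 and 162 averaged, 4 higher in the interaction, 630 and 455 between control stages and 425 and 225 between null-labelled stages. limma-voom called 31 and 26 between control stages and 21 higher between null-labelled stages. With only the groups compared in the fit, the counts were 140 and 57 at E13.5, 0 and 2 at E14.5, 231 and 99 between control stages and 15 and 4 between null-labelled stages. Without both null-labelled libraries numbered 1 they were 8 and 18 at E13.5, 2 and 11 at E14.5 and 47 higher averaged.

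With the replicate block within stages, the counts were 391 and 175 at E13.5, 342 and 122 at E14.5, 777 and 325 averaged and 5 and 8 in the interaction. All 58 and all 21 genes called at the stages were among them, as were 353 of 354 averaged, and 2 of 56 list calls were lost. Across stages the samples share only a number, and the block gave 930 and 677 between control stages and 597 and 390 between null-labelled stages. Control numbers correlated at 0.3, 0.04 and 0.16 there, and each exceeded the values with other numbers.

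With single libraries left out, the higher and lower counts ran from 1 to 85 and 6 to 50 at E13.5, 0 to 234 and 2 to 25 at E14.5, 99 to 562 and 39 to 117 averaged, 0 to 728 and 0 to 482 between control stages, and 0 to 199 and 0 to 67 between null-labelled stages. The interaction stayed at 0.

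The Fgf9 log2 fold change at E13.5 passed with the replicate block, at -1.13, and without a filter, at -1.2, and at E14.5 it ran from -0.68 to 0.26 with single libraries left out. Among log2 fold changes that had not passed, signs turned or reached 0 with the block for Cpa1 at E13.5 (0.07), Ddx3y at E13.5 (0), Etv4 at E14.5 (-0.2) and Gcg at E14.5 (0.1), and with limma-voom for Etv4 at E14.5 (-0.03). Without both null-labelled libraries numbered 1 they turned at E13.5 for Cpa1 (0.09) and Gcg (0), and at E14.5 for Etv4 (-0.63), Sox9 (0.01), Neurog3 (0.24), Cpa1 (0.23), Gcg (0.47), Onecut1 (0.04), Ihh (-4.19) and Trim29 (-0.01, and -0.74 averaged). The progenitor list at E14.5 and the acinar list averaged turned there too, with camera adjusted p of 0.86 and 0.29.

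With single libraries left out, signs turned or reached 0 at E13.5 for Cpa1 (-0.28 to 0.09), Gcg (-0.45 to 0.01), Neurog3 (-0.23 to 0.22), Pdx1 (-0.16 to 0.17), Sox9 (-0.24 to 0.48) and Fabp1 (0 to 5.67). At E14.5 they turned for Cpa1 (-1.08 to 0.23), Etv4 (-0.63 to 0.53), Fgfr3 (-0.01 to 0.68), Gcg (-0.85 to 0.47), Iapp (-0.17 to 0.83), Ihh (-4.18 to 6.13), Ins2 (-0.56 to 1.15), Neurog3 (-0.57 to 0.24), Onecut1 (-0.94 to 0.04), Pcsk1 (-0.29 to 1.14), Sox9 (-0.63 to 0.01) and Trim29 (0 to 2.89, and -0.31 to 1.14 averaged). Between control stages they turned for Uty (-0.06 to 0.62) and Xist (-0.54 to 0.43). Camera adjusted p of lists that turned ran from 8.3e-08 to 0.49 for acinar averaged, 2.7e-07 to 0.87 for progenitor at E14.5 and 1.6e-12 to 0.43 for skeletal muscle in the interaction.

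Depth of 17736769 to 22798257 counts limits genes of a few counts, such as Nkx2-5 in null-labelled libraries.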

Other observations

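The split of the libraries was examined with tests fixed before their results, apart from the remark on replicate number, which came after. Of the 100 ways to label 2 libraries per stage as null, 3 called as many genes as the real labels, the real one included, which called 354. With the replicate numbers ignored that share is under 0.05, but the highest other split called 2191 genes. The libraries are thus not interchangeable, and the share does not exclude chance. That split sets the 4 libraries numbered 1 against the rest, and points to a structure of the samples in which these stand apart. The split on the 4 libraries numbered 2 called 0 genes. The other split above the real one called 698 genes and set both E13.5 null-labelled libraries and both E14.5 libraries numbered 1 against the rest. With the replicate number as a block the real labels called 777 genes higher and 325 lower. With the numbers taken as pairs, among the 16 splits that part all 4 same-numbered pairs, 1 called as many genes, the real one, and the highest other called 0, but 16 splits are too few for a share under 0.05. The comparison of control stages has 10 splits, also too few. The real one called 211 genes and was the 1 split with as many, and the highest other called 0.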
